A study of Glycine max with 12 samples.

How the data were processed

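Small RNA libraries from 6 laser-captured subregions of globular-stage soybean seeds (Glycine max, cultivar Williams 82) were analysed, with 2 libraries per subregion, 12 in all. Seeds at this stage measured about 1 mm per the labels. The labels give 250 ng of RNA as input, 15 cycles of PCR and gel selection at 147 to 160 bp, and describe the dissection itself only for the embryo proper and the epidermis. Each deposited file holds counts, as whole numbers, of reads for every distinct sequence of 18 to 26 nt in 1 library. Bowtie was used per the submitters' processing notes; its version, the genome build, adapter trimming and read filters are not given in the sources used here. The files came in 2 layouts, with a header in 5 libraries (both of the endosperm, both of the epidermis and inner integument 2) and without in 7. The PCR reads carry no molecular identifiers, so count floors and other limits from counts cover counting error only.

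The 12 files were joined into 7691810 distinct sequences, of which 361896 had a total of at least 10 counts. Depth was 1780807 to 7514504 reads per library, at which 3 counts over the 2 libraries of a subregion, taken as the floor for a family with no read, correspond to less than 1 CPM. Reads were assigned to 40 listed families from 54 mature sequences: a read of 19 to 24 nt counted when it held bases 3 to 18 of a mature sequence and started within 4 nt of it, which gathered 646 sequences. The lists of families (developmental, nutrient and copper, small RNA machinery, phasiRNA triggers, other legume, tasiRNA) were fixed before the data were examined. Positions of substitutions are counted from 1 at the 5′ end of the listed mature sequence. A family with too few reads was not tested, which left out 6: miR169 (48 reads over all libraries), miR2109 (41), miR530 (1), miR828 (1), miR827 (0) and miR858 (0).

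Families and single sequences were fitted together in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1 and the data.table package (version 1.17.8). Low-count filtering by expression (minimum count 10, minimum total 15) kept 42733 of them, 34 families among these and 42697 sequences, and the kept ones held 48.1% to 81.5% of a library's reads. TMM factors ranged from 0.703 to 1.36. A model with 1 mean per subregion (6 residual degrees of freedom) was fitted by quasi-likelihood, and F tests were adjusted by the Benjamini-Hochberg method over all families and sequences of a comparison, with calls at an adjusted p of 0.05. The 9 comparisons were each subregion against the mean of the log2 levels of the other 5, seed coat against embryo proper and endosperm, embryo proper against endosperm, and hilum against the rest of the seed coat, beside a test across all 6 subregions. Standard errors were the size of the log2 fold change over the square root of F. Fitted fold changes used a prior count of 0.125. Where a subregion in the comparison had no read or up to 3 reads, they are not printed, except for miR2119 under the replicate number as a block, and levels or a lower bound from the floor are given instead.

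Families past the threshold were named, up to 10 per direction by size of change, with single sequences of at least 10 CPM in every library of the higher side, up to 3 per direction. miR156/miR157, miR165/miR166, miR167, miR172, TAS3 tasiR-ARF and the 21-, 22- and 24-nt classes were followed in every subregion. Shares of size classes, of first bases, and of rRNA ends and listed families were tested by an exact permutation F test over all ways to pair the 12 libraries, for which the smallest possible p is 9.62e-05, and adjusted within each group of shares. Lists were tested with camera (preset correlation 0.01, or estimated) and with fry, adjusted over 45 tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the joining, composition tests and figures.

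The model was tested on simulated data built from the libraries with known changes. For seed coat against embryo proper and endosperm it found 2%, 18%, 82% and 98% of changes of 2-, 4-, 8- and 16-fold, with 5 false among 105 calls. The hilum against the other subregions gave 2%, 16%, 66% and 94%, with 3 false among 92 calls, and embryo proper against endosperm gave 0%, 0%, 8% and 34%, with 0 false among 21 calls. In the simulated form of the last comparison, changes of 8-fold or less were mostly missed. Only 50 families or sequences changed at each size, against 13971 sequences called in the real comparison. The real fit also called smaller changes there, such as miR1507 at log2 -1.84, so the simulated shares are not limits for it.

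Alternatives chosen before the data were examined were RLE size factors, library size only, scaling to microRNA reads, a weak filter (total of at least 10), DESeq2 1.42.0, the replicate number as a block, exact mature sequences only, comparison within each kind of label, each library left out in turn, an estimated correlation, distinct sequences in place of reads, and size classes without the most abundant sequences or the listed families. Chosen after seeing the data were a term for file layout, counts divided by an estimate of reads per molecule, a near variant counted in miR156/miR157, lists with each library left out, leaving out the endosperm with epidermis 1, and size classes without rRNA ends. No genome was used, so siRNAs of the chalcone synthase locus, tRNA and rRNA fragments by origin, and 24-nt loci in genomic windows were not analysed here.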

Results

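Small RNAs of 18 to 26 nt were counted in 12 libraries from the developing seed of soybean (Glycine max, cultivar Williams 82). Seeds were taken at the globular stage, when the embryo is still a ball of cells without organs. The 6 subregions, with 2 libraries each, were the embryo proper and the endosperm, which arise from fertilization, and 4 parts of the maternal seed coat: the epidermis, the outer integument, the inner integument and the hilum, where the seed joins the pod. Library totals were 3922370 and 4673794 reads in the embryo proper, 2806981 and 1780807 in the endosperm, 3481781 and 2652433 in the epidermis, 7514504 and 4972264 in the outer integument, 3178547 and 2678358 in the inner integument, and 5373538 and 3443568 in the hilum. The labels call the libraries of a subregion biological replicates but do not say from which plants each came, so p-values measure the spread between these libraries. Values after ± are standard deviations over 2 libraries for levels and standard errors for log2 fold changes, and CPM are read counts scaled to library size.

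The 2 libraries of a subregion differed by more than counting error in every subregion, with a chi-square per degree of freedom of 72.8 in the embryo proper, 93.0 in the endosperm, 129 in the epidermis, 29.9 in the outer integument, 60.3 in the inner integument and 40.2 in the hilum. Pearson correlations of log2(CPM + 1) between the libraries of a subregion were 0.761, 0.557, 0.569, 0.849, 0.679 and 0.690 in the same order. The correlation between subregions had a median of 0.386 and a highest value of 0.717. In 4 of the 6 subregions each library lay closest to its own replicate. The exceptions were the epidermis, where a library reached 0.690 with a hilum library, and the hilum, where a library reached 0.717 with an outer integument library. Sequences read once made up 18.2% and 14% of the distinct sequences in the endosperm libraries, 14.1% in epidermis 1 and 29.7% in inner integument 2, against 49.7% to 69.0% in the other 8 libraries.

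The question of size classes was which lengths of small RNA each part of the seed carries. The 24-nt class, the length of siRNAs that direct DNA methylation, held 56.0 ± 2.01% of reads in the embryo proper and 53.2 ± 3.28% in the outer integument, against 40.6 ± 3.15% in the hilum, 40.4 ± 7.76% in the epidermis, 28.7 ± 0.710% in the endosperm and 24.5 ± 2.99% in the inner integument. The 21-nt class, the length of most microRNAs and of tasiRNAs, was largest in the endosperm at 35.2 ± 4.69% and smallest in the embryo proper at 9.01 ± 0.0453%, with 17.3 ± 3.14% in the epidermis, 16.5 ± 2.77% in the hilum, 12.5 ± 0.127% in the outer integument and 12.2 ± 1.08% in the inner integument. The 22-nt class, the length of many phasiRNA triggers, was largest in the inner integument at 20.2 ± 3.11%, followed by 15.5 ± 0.0615% in the hilum, 13.4 ± 2.00% in the outer integument, 11.2 ± 0.463% in the embryo proper, 11.2 ± 1.57% in the endosperm and 10.9 ± 1.82% in the epidermis. Shares differed across subregions in an exact permutation test over all pairings of libraries for the 24-nt class (adjusted p = 0.0173), the 21-nt class (0.0186), the 22-nt class (0.0310) and the 18-nt class (0.0310), which makes 4 of 9 classes. The count fell to 2 of 9 without embryo proper 1, embryo proper 4, endosperm 4, outer integument 2, hilum 1 or hilum 2, and rose to 6 without epidermis 1. It was 9 when each distinct sequence counted once or when the 10 most abundant sequences were left out. Without reads from rRNA ends the order of subregions changed. The 22-nt share was 14.9 ± 1.64% in the inner integument, 10.8 ± 0.108% in the outer integument, 10.6 ± 1.39% in the endosperm, 10.4 ± 0.263% in the hilum, 10.1 ± 0.354% in the embryo proper and 7.91 ± 0.886% in the epidermis. The lowest 24-nt share was then that of the endosperm, 32.2 ± 2.64%, with 34.2 ± 4.87% in the inner integument.

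**Figure D1:**
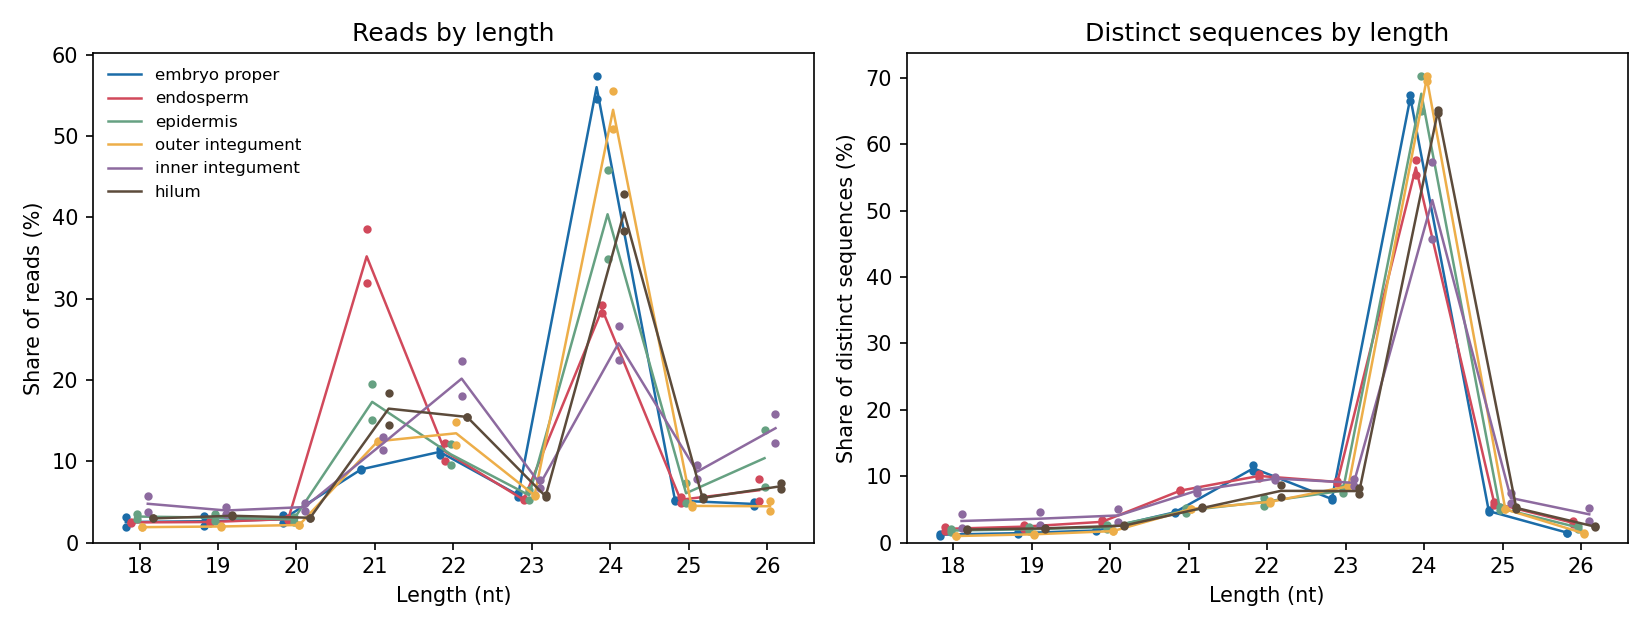
Share of reads (%) and share of distinct sequences (%) against length (18 to 26 nt) in the 6 subregions. Points are libraries and lines join the means of 2 libraries.

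The first base of a small RNA guides which Argonaute protein takes it up. Reads from rRNA ends were counted in the first-base shares, which were not computed without them. Among 24-nt reads, A came first in 52.3 ± 1.03% in the embryo proper and in 29.9 ± 1.98% in the inner integument (adjusted p = 0.000924). Among 21-nt reads, U (T in the files) came first in 78.2 ± 3.95% in the endosperm and in 32.0 ± 2.52% in the inner integument (adjusted p = 0.000924), where A came first in 32.9 ± 0.750% against 4.38 ± 0.928% in the endosperm (adjusted p = 0.000770). All 12 shares of a first base in the 21-, 22- and 24-nt classes differed across subregions in the exact permutation test, 6 of 12 without the 10 most abundant sequences, where the 21-nt share of U was not called (adjusted p = 0.129). The count was 8 of 12 without embryo proper 1. Reads of the listed microRNA and tasiRNA families made up 29.2 ± 4.73% of the endosperm libraries, 11.7 ± 3.38% of the epidermis, 11.5 ± 2.16% of the hilum, 8.09 ± 0.483% of the outer integument, 8.01 ± 2.13% of the inner integument and 5.24 ± 0.0358% of the embryo proper (adjusted p = 0.0231, exact permutation test). Reads from the end of 5S ribosomal RNA made up 32.2 ± 0.942% of the inner integument libraries, 17.5 ± 8.98% of the epidermis, 15.9 ± 1.22% of the hilum, 10.7 ± 5.45% of the endosperm, 10.2 ± 3.55% of the outer integument and 5.76 ± 1.01% of the embryo proper (adjusted p = 0.0331, exact permutation test). The share from the end of 18S rRNA was not called (adjusted p = 0.0701, same test). Such reads can be a sign of RNA breakdown, which was not tested.

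Which families differ anywhere in the seed was asked with a test across all 6 subregions (edgeR quasi-likelihood, Benjamini-Hochberg adjustment over 42733 families and sequences). Of 34 families, 31 differed, and the same 31 passed when adjusted over the list alone. They were all 13 developmental families, all 7 nutrient and copper families, all 3 families of the small RNA machinery, 4 of 6 phasiRNA triggers, 3 of 4 other legume families and the TAS3 tasiRNA. miR1510, miR1514 and miR1515 were not called (adjusted p = 0.630, 0.406 and 0.511). miR165/miR166, which limits class III HD-ZIP factors in the shaping of organs, was the most abundant of the 5 families followed in every subregion, with 262168 ± 4226 CPM in the endosperm, 89786 ± 12880 in the epidermis, 81686 ± 37726 in the hilum, 52340 ± 4310 in the embryo proper, 31451 ± 2027 in the outer integument and 22666 ± 5483 in the inner integument (adjusted p = 0.00286). That call was lost when counts were scaled to microRNA reads, at adjusted p = 0.140, and with file layout as a term. miR156/miR157, miR172, miR167 and TAS3 differed at adjusted p = 1.01e-17, 3.90e-17, 3.77e-10 and 1.97e-08. Among single sequences 25969 of 42697 (60.8%) differed. Fits with 1 library left out tested 75311 to 83656 sequences, since the filter's smallest group was then 1 library. Counts of sequences given below for such fits are therefore not out of 42697, and they mix the change of filter with the loss of a library.

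**Figure D2:**
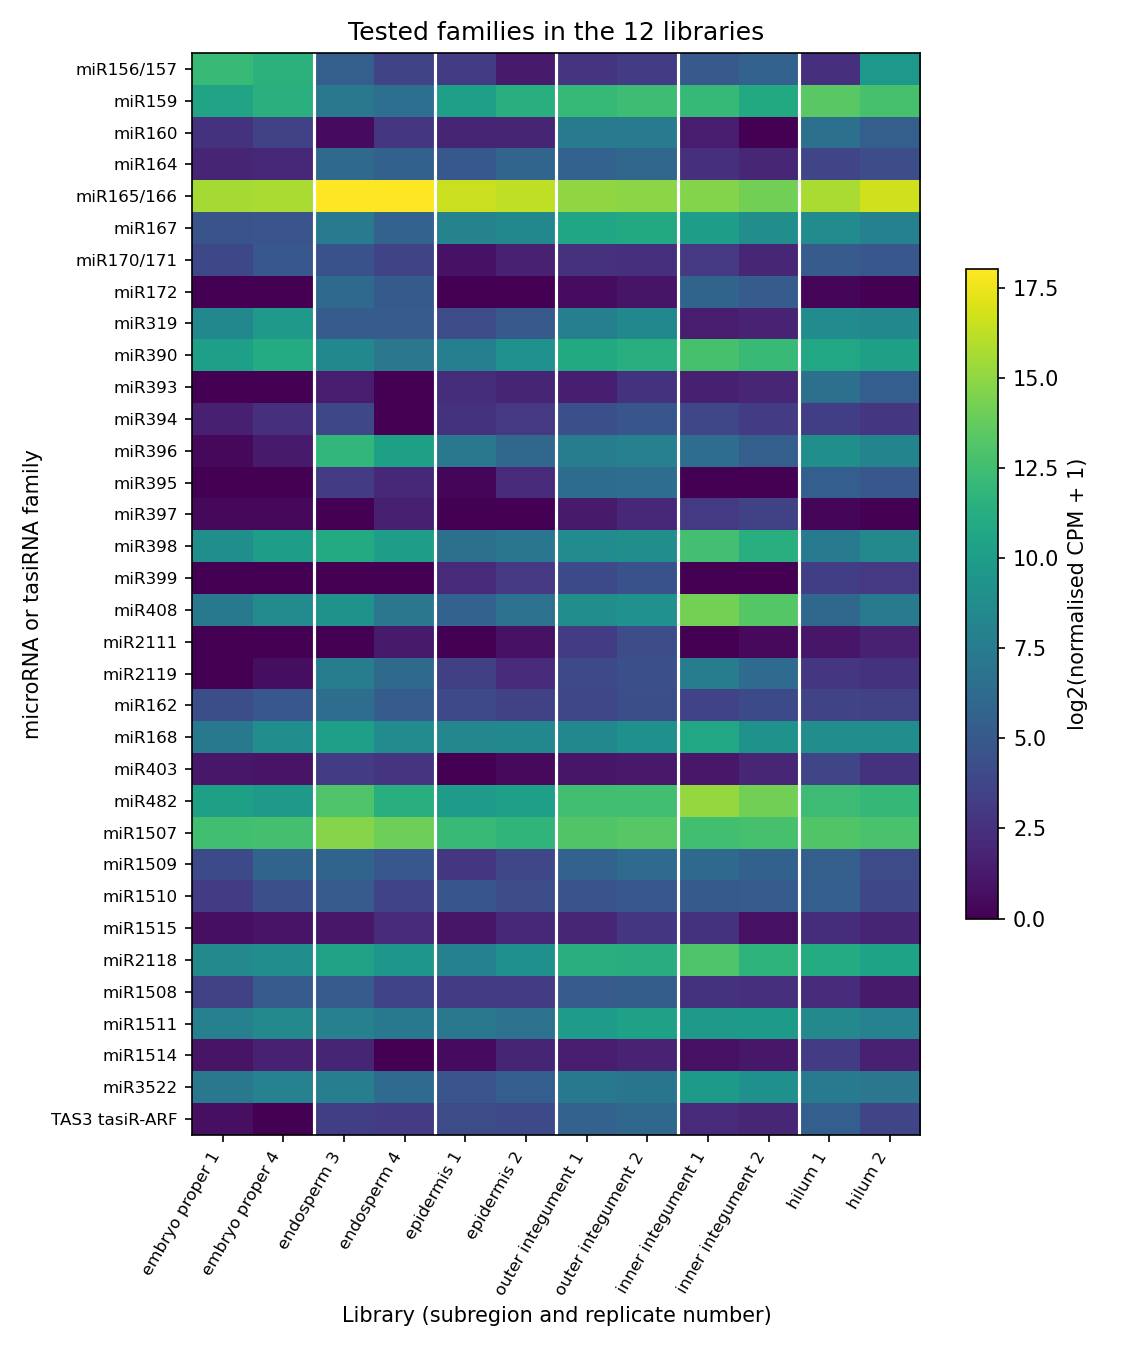
Log2(normalised CPM + 1) of 34 families (vertical) in 12 libraries (horizontal), ordered by subregion. Colour gives the level of a family in 1 library.

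**Figure D3:**
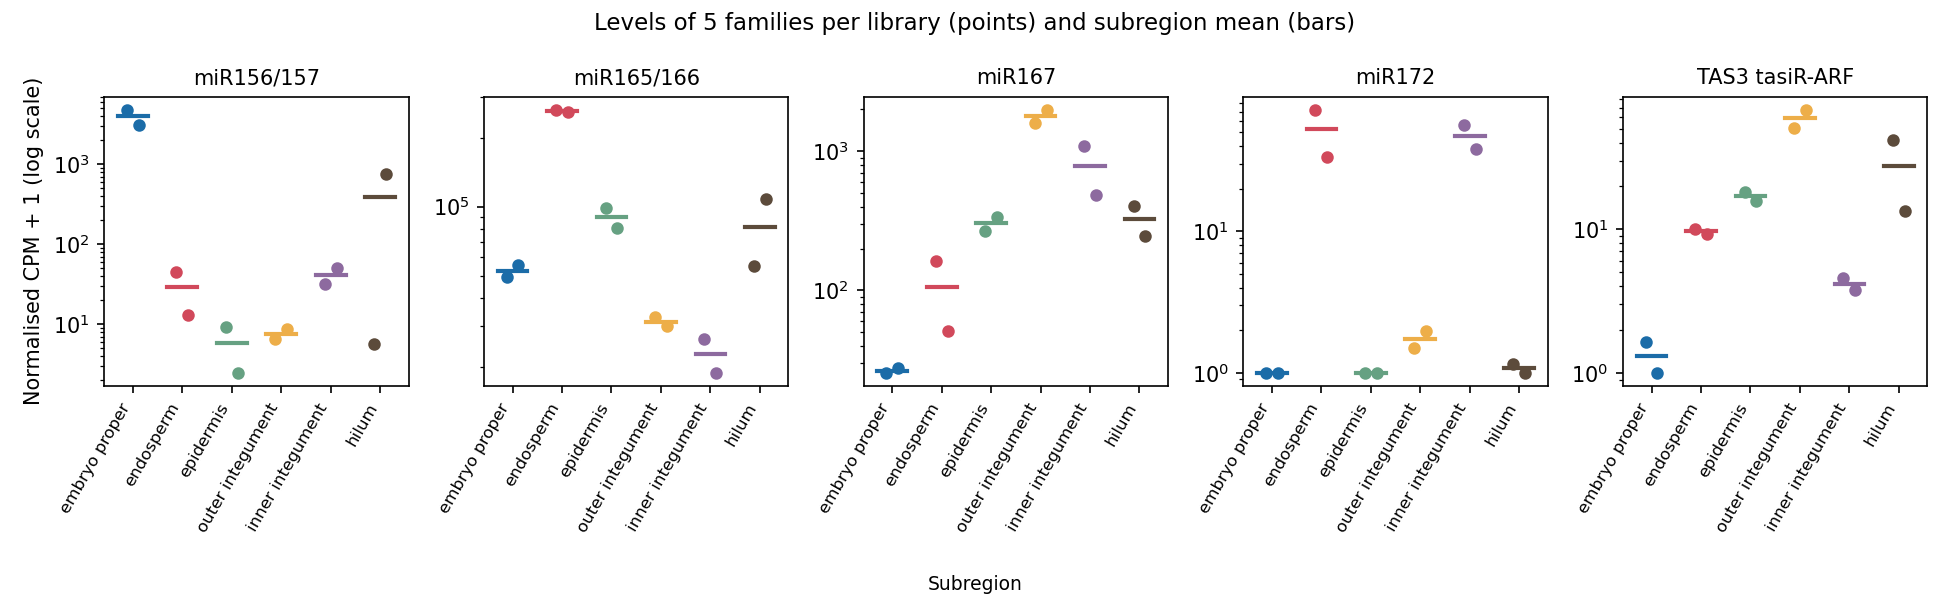
Normalised CPM + 1 (log scale) of miR156/miR157, miR165/miR166, miR167, miR172 and TAS3 tasiR-ARF in the 6 subregions. Points are libraries and bars are means of 2 libraries.

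The embryo proper was compared with the mean of the other 5 subregions to find what marks the early embryo. miR156/miR157, which holds back SPL factors and adult traits, stood 146-fold higher (log2 7.19 ± 0.52, adjusted p = 8.64e-19), at 3969 ± 1203 CPM against 384 ± 537 in the hilum, 40.2 ± 12.7 in the inner integument, 28.0 ± 22.4 in the endosperm, 6.66 ± 1.66 in the outer integument and 4.89 ± 4.84 in the epidermis. With the near variant TTGACAGAAGAGAGAGAGCAC counted in the family, log2 was 6.20 ± 0.50. miR319, which limits TCP growth factors, was higher by log2 3.71 ± 0.41 (adjusted p = 1.60e-11), and so was miR170/miR171, which targets SCARECROW-like factors, by log2 1.59 ± 0.53 (adjusted p = 0.0137). miR396, which limits growth-regulating factors, fell (log2 -8.14 ± 0.91, adjusted p = 2.67e-11), to 0.922 CPM. miR167, which limits auxin response factors, fell (log2 -4.07 ± 0.67, adjusted p = 7.23e-07), to 25.5 ± 1.42 CPM, and TAS3, whose tasiRNAs act on another group of auxin response factors, left 2 reads (adjusted p = 3.90e-06). miR393, which targets auxin receptors, left no read (adjusted p = 0.000106), and miR2119, which acts on alcohol dehydrogenase in legumes, left 2 reads (adjusted p = 1.07e-07). miR164, which limits NAC boundary factors, fell (log2 -3.11 ± 0.69, adjusted p = 0.000166), and the disease-resistance gene regulators miR482 and miR2118 fell (log2 -2.39 ± 0.66 and -1.96 ± 0.60, adjusted p = 0.00277 and 0.00691).

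Of the families tested in the embryo proper, 3 rose and 8 fell of 34. Among developmental families 3 rose, 4 fell and 6 of 13 were not called, 1 of 7 nutrient and copper families fell, 2 of 6 phasiRNA triggers fell, and TAS3 fell. No machinery family (of 3) or other legume family (of 4) was called. Adjusted over the list alone the count was also 11. miR165/miR166 was not called (log2 -0.36, adjusted p = 0.816), nor was miR172, with no read in the embryo. The call of miR170/miR171 held in 4 of 12 sets with 1 library left out (adjusted p = 0.611 without embryo proper 4), and that of miR393 in 11 (adjusted p = 1.00 without endosperm 3). Among sequences 9537 were higher and 5961 lower, but 1402 and 3766 with file layout as a term and 52494 and 5274 with the weak filter. Scaling by library size gave 8069 higher and 8269 lower sequences, and 2 higher and 13 lower families, while scaling to microRNA reads gave 5 and 7 families. Leaving out a library of the endosperm, epidermis, inner integument or hilum put the called sequences between 24114 and 26953. The 21-nt GCTCACTCTCTATCTGTCACC reached 111 ± 14 CPM in the embryo proper and had 36 reads elsewhere, all in hilum 2, and AGATAGACACACCCTTGGGCT had none in the embryo against 208 ± 197 CPM in the other libraries.

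The endosperm was set against the other 5 subregions to find regulators of the tissue that feeds the embryo. miR172, which limits AP2-like factors, reached 52.0 ± 27.3 CPM, at least 111-fold above the embryo proper and at least 126-fold above the epidermis, where no read was found (adjusted p = 6.82e-17). miR396 was higher by log2 5.51 ± 0.42 (adjusted p = 4.00e-19), at 2554 ± 1870 CPM, and miR2119 stood at 128 ± 79.3 CPM (adjusted p = 1.21e-11). The inner integument reached similar levels of miR172 and miR2119, with miR172 at 45.9 CPM. miR165/miR166 was higher by log2 2.43 ± 0.56 (adjusted p = 0.000492), miR164 by 2.23 ± 0.46 (7.34e-05) and miR162, which targets Dicer, by 2.02 ± 0.47 (0.000524). miR403, which targets an Argonaute, stood at 7.01 ± 1.63 CPM (adjusted p = 0.0189). The resistance gene regulator miR1507 was higher by log2 1.75 ± 0.49 (adjusted p = 0.00487) and miR398, which limits copper superoxide dismutase, by 1.55 ± 0.45 (0.00859), but scaling to microRNA reads turned these to -0.11 and -0.25. miR159, which limits GAMYB factors and is needed for endosperm growth, fell (log2 -4.87 ± 0.76, adjusted p = 1.40e-07), to 121 ± 38.2 CPM. miR390, which triggers TAS3 tasiRNAs, fell (log2 -2.79 ± 0.64, adjusted p = 0.000424), and miR167 (-1.62 ± 0.56, 0.0337).

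In the endosperm 9 families rose and 3 fell of 34, or 15 in all when adjusted over the list alone. By list, 4 of 13 developmental families rose and 3 fell, 2 of 7 nutrient and copper families rose, 2 of 3 machinery families rose, 1 of 6 phasiRNA triggers rose, and TAS3 and the 4 other legume families were not called. Scaled to microRNA reads, 3 rose and 12 fell, and with the weak filter 4 and 9. In 8 of 12 sets with 1 library left out more fell than rose, as without endosperm 3, where 4 rose and 6 fell. miR156/miR157 in its listed forms (log2 -1.38, adjusted p = 0.165) and TAS3 (8.66 ± 0.513 CPM, adjusted p = 1.00) were not called. TTGACAGAAGAGAGAGAGCAC, which carries T14A relative to the listed miR156 (positions from 1 at its 5′ end) and was not counted in miR156/miR157, reached 715 ± 235 CPM in the endosperm and at most 1.09 CPM elsewhere, so the family's level covers only the listed forms. Counted in the family, it made miR156/miR157 higher in the endosperm (log2 3.30 ± 0.50, adjusted p = 9.11e-08). CGCCCCGTTGCATCGAACAAG reached 275 ± 156 CPM and was read in no other subregion. Without endosperm 3 the calls of miR403 (adjusted p = 0.456, kept in 1 of 12 sets), miR398 (1.00, kept in 2), miR162 (0.887, kept in 3), miR164 (0.340, kept in 7) and miR1507 (0.645, kept in 9) were lost, and without endosperm 4 that of miR167 (0.186). Sequences counted 5638 higher and 1716 lower, 7354 in all, against 4507 without endosperm 3, 4839 without endosperm 4 and 11192 without inner integument 2.

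The epidermis, the outermost cell layer of the seed coat, was compared with the other 5 subregions. It was marked more by low than by high families. miR156/miR157 fell (log2 -4.33 ± 0.86, adjusted p = 0.000895), miR170/miR171 (-3.04 ± 0.78, 0.0136), miR390 (-1.98 ± 0.60, 0.0383) and miR319 (-1.84 ± 0.57, 0.0434). The copper families miR408, which limits laccases and plantacyanin, and miR398 fell (log2 -3.02 ± 0.68 and -2.98 ± 0.64, adjusted p = 0.00442 and 0.00247). Among phasiRNA triggers, the families that fell were miR482 (log2 -2.37 ± 0.66, adjusted p = 0.0239), miR1509 (-2.19 ± 0.63, 0.0293) and miR2118 (-2.05 ± 0.60, 0.0318), as did the legume family miR3522 (-2.69 ± 0.60, 0.00385). miR399, which acts on phosphate uptake, was called higher than the mean of the other subregions (adjusted p = 0.00853). It stood at 5.24 ± 2.46 CPM, at least 11.2-fold above the embryo proper. The outer integument and hilum held more, at 18.9 and 8.04 CPM, while the embryo proper, endosperm and inner integument had no read. miR164 was higher by log2 1.65 ± 0.47 (adjusted p = 0.0276).

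Of 34 families in the epidermis 2 rose and 11 fell, 15 in all when adjusted over the list alone. Among developmental families 1 rose and 4 fell of 13, among nutrient and copper families 1 rose and 2 fell of 7, 3 of 6 phasiRNA triggers and 2 of 4 other legume families fell. TAS3 and the 3 machinery families were not called. miR165/miR166 (log2 0.57, adjusted p = 0.691), miR167 (0.21, 0.946) and TAS3 (15.9 ± 1.68 CPM, 0.174) were not called, and miR172 had no read. The count fell to 4 families without epidermis 1 and to 7 without epidermis 2, outer integument 1 or outer integument 2. Without epidermis 1 the calls of miR170/miR171 (adjusted p = 0.564, kept in 6 of 12 sets), miR319 (0.616, kept in 3), miR1509 (0.639, kept in 3), miR390 (0.371), miR2118 (0.296) and miR3522 (0.235) were lost, and without epidermis 2 those of miR399 (0.10, kept in 8) and miR164 (0.539, kept in 3). TTGGGCTTCAATTTCTTGACC reached 60.5 ± 16.3 CPM in the epidermis, against 33.5 ± 2.92 in the outer integument and at most 0.596 in the other 4 subregions. Sequences counted 1904 higher and 147 lower (541 and 187 in DESeq2), 2051 in all, against 133 without epidermis 1, between 281 and 811 without epidermis 2, outer integument 1, outer integument 2 or hilum 2, 1259 without embryo proper 1, 3662 without inner integument 1, and 1138 without hilum 1.

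The outer integument was compared with the other 5 subregions. miR395, which limits sulfate assimilation, stood at 84.6 ± 2.77 CPM, at least 180-fold above the embryo proper and at least 142-fold above the inner integument (adjusted p = 1.14e-13). miR399 stood at 18.9 ± 5.12 CPM, at least 40.3-fold above the embryo proper (adjusted p = 6.11e-08), and miR2111, a phosphate and nodulation signal, at 13.2 ± 6.93 CPM, at least 28.2-fold above the embryo proper (adjusted p = 2.49e-06). The auxin response factor regulators miR160 and miR167 were higher by log2 5.01 ± 0.46 (adjusted p = 2.76e-13) and 3.29 ± 0.41 (1.09e-08), and TAS3, on yet other factors of that class, stood at 58.3 ± 12.1 CPM, the highest of the 6 subregions (adjusted p = 3.57e-07). miR319 was higher by log2 2.40 ± 0.42 (adjusted p = 5.28e-05), though counting exact mature sequences alone turned this to -1.27. miR164 was higher by log2 2.03 ± 0.46 (adjusted p = 0.00160), and the legume families miR1508 and miR1511 by 2.04 ± 0.50 (0.00336) and 1.98 ± 0.42 (0.000769). miR156/miR157 fell (log2 -3.87 ± 0.82, adjusted p = 0.000824).

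Of the 34 families in the outer integument 12 rose and 1 fell, 17 in all when adjusted over the list alone. By list, 6 of 13 developmental families rose and 1 fell, 3 of 7 nutrient and copper families, 2 of 4 other legume families and TAS3 rose. None of 3 machinery families or 6 phasiRNA triggers was called. miR165/miR166 was not called (log2 -1.24, adjusted p = 0.227), nor was miR172, at 0.735 ± 0.346 CPM. All 11 families named here kept their calls with any 1 library left out, but none did with file layout as a term, where 3 sequences were called. All 11 kept their sign with that term, but for miR395 and miR399 it could not be estimated (standard errors of 10022 and 13974). The kept sign of these 2 carries no information. miR160 went from log2 5.01 to 2.53 ± 60.8, miR167 from 3.29 to 2.73 ± 0.71 and miR319 from 2.40 to 2.70 ± 0.79. With any 1 library left out, in contrast, the count of families rose above 13. TTGAGGGACCAACATTGCATGA, of 22 nt, reached 39.3 ± 5.83 CPM against 0.914 elsewhere. Sequences counted 6412 higher and 1090 lower, 7502 in all. With the replicate number as a block 1214 were called, and 466 of these were higher, so the majority turned to lower. Leaving out embryo proper 1, endosperm 3 or 4, epidermis 1 or 2, inner integument 1, or hilum 1 or 2 gave 14660 to 26636.

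The inner integument, which borders the endosperm, was compared with the other 5 subregions. miR408 was higher by log2 6.09 ± 0.45 (adjusted p = 1.27e-18), at 14896 ± 6794 CPM, miR398 by 3.29 ± 0.42 (7.13e-09), and miR397, which limits laccases, stood at 9.12 ± 2.27 CPM, at least 22.2-fold above the epidermis (adjusted p = 4.35e-05). miR2119 stood at 132 ± 75.8 CPM (adjusted p = 9.54e-11). miR172 reached 45.9 ± 12.7 CPM, at least 97.8-fold above the embryo proper (adjusted p = 7.38e-15). Both families stood at similar levels in the endosperm, where miR172 was at 52.0 CPM. The resistance gene regulators miR482 and miR2118 were higher by log2 3.30 ± 0.46 (adjusted p = 7.17e-08) and 2.63 ± 0.44 (5.00e-06), as were miR390 by 2.76 ± 0.44 (1.66e-06), miR3522 by 2.60 ± 0.41 (1.91e-06) and miR167 by 1.86 ± 0.44 (0.00153). miR319 fell (log2 -6.12 ± 0.78, adjusted p = 7.16e-09), to 1.98 ± 0.566 CPM, miR160 (-4.22 ± 0.87, 0.000281) and miR164 (-2.61 ± 0.67, 0.00469).

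Of 34 families in the inner integument 12 rose and 3 fell (11 and 5 in DESeq2), 16 in all when adjusted over the list alone. By list, 3 of 13 developmental families rose and 3 fell, and 4 of 7 nutrient and copper families, 1 of 3 machinery families, 2 of 6 phasiRNA triggers and 2 of 4 other legume families rose. miR156/miR157 (log2 -0.76, adjusted p = 0.585), miR165/miR166 (-1.81, 0.12) and TAS3 (3.17 ± 0.551 CPM, 0.173) were not called. Without inner integument 1 the calls of miR2118 (adjusted p = 0.0778), miR167 (0.472, kept in 9 of 12 sets) and miR164 (0.111) were lost, and without inner integument 2 those of miR160 (0.0936) and miR164 (0.295). GGAATGGGCTGATTGGGAAGC, from the arm of the miR482 hairpin opposite to the listed form, was lower at 274 ± 91.9 CPM than the 7235 ± 5534 CPM of the other 10 libraries together. It was lowest in the embryo proper, at 16.7 ± 1.77 CPM, against 5324 to 12540 in the other 4 subregions. Sequences counted 3898 higher and 385 lower (2716 and 687 with RLE size factors, 1172 and 680 in DESeq2), 4283 in all. Their number fell to 2311 without embryo proper 1, 2619 and 2813 without epidermis 1 and 2, 1560 and 1176 without outer integument 1 and 2, 1726 without inner integument 1, and 1953 and 1935 without hilum 1 and 2.

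The hilum, through which the seed is supplied, was compared with the other 5 subregions. miR393 stood at 69.4 ± 40.3 CPM, at least 148-fold above the embryo proper (adjusted p = 2.98e-13), and the auxin response factor regulator miR160 was higher by log2 3.52 ± 0.48 (adjusted p = 2.35e-07). miR395 and miR399 stood at 35.0 ± 8.12 and 8.04 ± 1.32 CPM, at least 74.6-fold and 17.1-fold above the embryo proper (adjusted p = 1.69e-08 and 0.000320). The outer integument held more of both, at 84.6 and 18.9 CPM, and a larger change of miR160 (log2 5.01). miR319, miR159, miR396 and miR170/miR171 were higher by log2 2.97 ± 0.42 (adjusted p = 5.40e-07), 2.60 ± 0.45 (5.42e-05), 2.27 ± 0.45 (0.000573) and 2.25 ± 0.50 (0.00296). miR403 stood at 9.03 ± 5.23 CPM (adjusted p = 0.00899) and TAS3 at 26.4 ± 19.8 CPM (0.00757). The legume family miR1508 fell (log2 -2.43 ± 0.70, adjusted p = 0.0277), as did miR408 (-2.23 ± 0.64, 0.0274). miR156/miR157 was higher by log2 3.15 ± 0.51 (adjusted p = 1.89e-05), but its levels were 4.73 CPM in hilum 1 and 764 CPM in hilum 2, and without hilum 2 it was lower at log2 -2.84 (adjusted p = 0.0197). Over 170 sequences with at least 10 CPM in both embryo libraries and levels more than 20-fold lower in the 8 libraries outside embryo and hilum, the median level in hilum 2 was 12.8% of that in the embryo, against 0.230% in hilum 1.

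Of 34 families in the hilum 11 rose and 2 fell, 14 in all when adjusted over the list alone. By list, 7 of 13 developmental families, 2 of 7 nutrient and copper families, 1 of 3 machinery families and TAS3 rose, 1 nutrient and copper family and 1 of 4 other legume families fell, and none of 6 phasiRNA triggers was called. miR165/miR166 (log2 0.41, adjusted p = 0.788) and miR167 (0.33, 0.771) were not called, and miR172 had 1 read. The calls of miR403 (adjusted p = 0.180) and miR408 (0.299) were lost without hilum 1, and that of miR1508 without hilum 2 (0.493, kept in 3 of 12 sets). The 22-nt TATTTTCGGAGTCCTGGAGCCT reached 91.0 ± 41.3 CPM, against 8.08 ± 3.22 in the embryo proper, 7.78 ± 1.07 in the outer integument and at most 0.512 in the other 3 subregions. Sequences counted 2254 higher and 71 lower (375 and 128 in DESeq2), 2325 in all, against 1452 without hilum 1, 5348 without embryo proper 1, 9398 and 7429 without endosperm 3 and 4, 5133 and 7762 without epidermis 1 and 2, and 6123 and 3826 without inner integument 1 and 2.

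The seed coat as a whole, 8 libraries, was compared with the embryo proper and endosperm, 4 libraries, to separate maternal from filial small RNAs. miR167, log2 3.56 ± 0.48 (adjusted p = 1.06e-08), miR160, 1.32 ± 0.54 (0.0450), and miR390, 1.39 ± 0.43 (0.00934), were higher in the coat, as were TAS3 (adjusted p = 2.88e-05) and miR393 (7.17e-06). miR159 was higher by log2 3.00 ± 0.49 (adjusted p = 1.98e-06), miR396 by 1.64 ± 0.49 (0.00630), miR2118 by 1.45 ± 0.44 (0.00678) and miR482 by 1.2 ± 0.46 (0.0362), and miR2119 passed too (0.0475). In the coat miR156/miR157 fell (log2 -3.63 ± 0.48, adjusted p = 8.97e-09), miR170/miR171 (-1.75 ± 0.46, 0.00206), miR319 (-1.62 ± 0.38, 0.000800), miR1508 (-1.55 ± 0.44, 0.00471), miR162 (-1.52 ± 0.41, 0.00284), miR165/miR166 (-1.29 ± 0.50, 0.0351) and miR398 (-1.2 ± 0.39, 0.0129). Of 34 families 10 rose and 7 fell, 18 in all when adjusted over the list alone. By list, 6 of 13 developmental families rose and 4 fell, 1 of 7 nutrient and copper families rose and 1 fell, 2 of 6 phasiRNA triggers and TAS3 rose, and 1 of 3 machinery families and 1 of 4 other legume families fell. Sequences counted 10188 higher and 5598 lower, but 5995 and 6645 within the labels that describe the dissection. With the replicate number as a block 5 families and 901 sequences were called, and 191 of these sequences were higher. Without the endosperm and epidermis 1 the coat had 16094 higher and 22326 lower. Scaling by library size gave 14 higher and 5 lower families, and scaling to microRNA reads gave 17 and 1.

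The labels describe the dissection only for the embryo proper and the epidermis, so coat and filial libraries were also compared within each kind of label. Epidermis against embryo proper gave 11 families and 12640 sequences, and the other coat parts against the endosperm gave 16 families and 11153 sequences. Within the libraries with a described dissection miR160 (log2 -1.07), miR390 (-1.68) and miR165/miR166 (1.28, adjusted p = 0.549) took the opposite sign. Within the rest miR396 (log2 -3.70, adjusted p = 2.53e-08) and miR2119 (adjusted p = 3.91e-05) were lower in the coat, and miR156/miR157 (0.91, 0.398) and miR319 (0.84, 0.128) were not called. The difference between the 2 kinds of label was not tested. Within the libraries with a described dissection the embryo proper files had no header and the epidermis files had a header. Coat and file layout cannot be told apart there. Within the rest both endosperm files had a header, and of the coat files only that of inner integument 2 did. With 1 library left out the calls of miR398 (kept in none of 12 sets, adjusted p = 0.769), miR1508 (kept in 2, 0.702), miR162 (kept in 2, 0.433), miR170/miR171 (kept in 3, 0.218) and miR165/miR166 (kept in 8, 0.157) were lost without endosperm 3, and those of miR319 (kept in 7, 0.146), miR2119 (kept in 9, 0.0960) and miR160 (kept in 10, 1.00) without embryo proper 4, embryo proper 1 and inner integument 1 in that order. AAACTGCAGAATCTCAATTTAAAT, of 24 nt, reached 536 ± 3.12 CPM in the endosperm and 25.2 ± 2.32 in the embryo proper against 1.38 CPM in the coat, and GAAGTGACTGTCGGAGCCTGC reached 65.2 ± 37.4 CPM in the coat against 0.430 CPM.

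The embryo proper was compared with the endosperm, 2 libraries each, to ask how the products of fertilization differ. miR156/miR157 was higher in the embryo by log2 7.14 ± 1.03 (adjusted p = 8.60e-07), though by 2.42 ± 0.81 (0.0173) with TTGACAGAAGAGAGAGAGCAC, at 715 ± 235 CPM in the endosperm, counted in the family. Also higher were miR159 by 4.12 ± 0.77 (adjusted p = 9.44e-05), miR319 by 4.04 ± 0.71 (3.22e-05) and miR390 by 2.79 ± 0.71 (0.00324). miR396 fell (log2 -11.37 ± 1.04, adjusted p = 2.96e-13), as did miR164 (-4.45 ± 0.80, 4.66e-05). miR172 and miR395, at least 111-fold and 11.4-fold higher in the endosperm (adjusted p = 1.85e-07 and 0.000629), had no read in the embryo, and miR2119 and TAS3 had 2 reads each there (adjusted p = 1.19e-08 and 0.00106). miR482 fell (log2 -2.41 ± 0.75, adjusted p = 0.0108), as did miR165/miR166 (-2.32 ± 0.89, 0.0363). miR167 fell (-2.05 ± 0.67, 0.0145), as did miR1507 (-1.84 ± 0.73, 0.0438), but scaling to microRNA reads turned these to 0.069 and 0.26. Of 34 families 4 rose and 10 fell, 15 in all when adjusted over the list alone. By list, 4 of 13 developmental families rose and 5 fell, 2 of 7 nutrient and copper families, 2 of 6 phasiRNA triggers and TAS3 fell, and no machinery or other legume family was called. Scaled to microRNA reads, 11 rose and 5 fell.

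CATGTGCCCCCCTTCCCCATC was the most abundant of the single sequences named for the embryo and endosperm, at 5026 ± 3048 CPM in the endosperm with 2 reads in the embryo proper. AGCCTTCGCCGACCGTCGTATAGT, of 24 nt, reached 114 ± 45.5 CPM in the embryo with no read in the endosperm. Of 42697 sequences 7084 were higher and 6887 lower in the embryo, 13971 in all. The balance varied: 3792 and 939 with the weak filter, 187 and 750 with file layout as a term, 3544 and 4108 in DESeq2, 3744 and 935 without embryo proper 1, and 2900 and 1137 without embryo proper 4. The count fell to 4679 and 4037 in the last 2, to 5410 and 4874 without endosperm 3 and 4, and to 7002 and 7583 without outer integument 1 and 2. Without endosperm 3 the calls of miR167 (adjusted p = 0.747, kept in 7 of 12 sets), miR1507 (0.347, kept in 7), miR482 (0.464, kept in 10) and miR165/miR166 (0.0654, kept in 10) were lost, and without embryo proper 4 that of TAS3 (0.0918).

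The hilum was compared with the other 3 parts of the seed coat to find what sets the point of attachment apart. miR393 was higher by log2 4.50 ± 0.58 (adjusted p = 2.51e-07), miR319 by 4.02 ± 0.48 (2.07e-08), miR160 by 3.33 ± 0.56 (0.000122), miR170/miR171 by 3.28 ± 0.57 (0.000176) and miR396 by 1.80 ± 0.49 (0.0462). miR395 was called higher than the mean of the 3 other parts (adjusted p = 0.000176), and miR403 was also higher (0.0109). At 35.0 CPM, miR395 was at least 59.0-fold above the inner integument, where it had no read, but below the 84.6 CPM of the outer integument. For miR160 too the outer integument was higher, at log2 5.01 against 3.52 in the hilum, each against the other subregions. miR408 fell (log2 -2.78 ± 0.68, adjusted p = 0.0206). miR156/miR157 was higher by log2 5.11 ± 0.60 (adjusted p = 2.00e-08), which without hilum 2 became -1.05 (adjusted p = 1.00). Of 34 families 8 rose and 1 fell (7 and 2 with RLE size factors, 7 and 3 in DESeq2), 13 in all when adjusted over the list alone. By list, 6 of 13 developmental families, 1 of 7 nutrient and copper families and 1 of 3 machinery families rose, 1 nutrient and copper family fell, and no phasiRNA trigger (of 6), other legume family (of 4) or TAS3 was called. miR165/miR166 (log2 1.03, adjusted p = 0.551), miR167 (-1.22, 0.336) and TAS3 (0.89, 0.548) were not called, and miR172 was nearly absent from the hilum. Without hilum 1 the calls of miR403 (adjusted p = 0.190, kept in 8 of 12 sets), miR396 (0.159, kept in 8) and miR408 (0.110) were lost.

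The 22-nt TTGGGTCGGAATTAGTCAAGCT reached 13.8 ± 2.82 CPM in the hilum against 0.414 in the rest of the coat. ATGGCGGAATCAGTACCTGGATGC, of 24 nt, went the other way, with 5 reads in the hilum against 43.1 ± 31.0 CPM in the rest. Sequences counted 365 higher and 59 lower in the hilum (120 and 190 in DESeq2), 424 in all. That count became 1197 and 1164 without endosperm 3 and 4, at most 228 without epidermis 1, outer integument 1 or outer integument 2, 774 without hilum 1 and 114 without hilum 2.

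The files came in 2 layouts, and the inner integument is the only subregion with 1 library of each, so layout and subregion overlap. With layout as a term, estimated from those 2 libraries, the embryo proper kept 10 of its 11 family calls, the inner integument 14 of 15, the seed coat against filial parts 13 of 17, and the test across subregions 27 of 31. The endosperm kept 4 of 12, the embryo against endosperm 5 of 14 and the hilum 1 of 13. The epidermis, the outer integument and the hilum against the rest of the coat kept 0 in edgeR, with 9, 10 and 10 families at an unadjusted p under 0.05. All named families kept the sign of their change. The median standard error went from 0.64 to 0.93 in the epidermis, from 0.49 to 0.85 in the outer integument, from 0.54 to 0.98 in the hilum and from 0.58 to 1.02 against the rest of the coat. miR319, for example, went from 2.40 ± 0.42 to 2.70 ± 0.79 in the outer integument, and miR398 from -2.98 ± 0.64 to -2.02 ± 0.85 in the epidermis. Other changes shrank: miR160 went from 1.32 ± 0.54 to 0.13 ± 0.44 in the seed coat against filial parts (adjusted p = 1.00), and miR2118 from -2.05 ± 0.60 to -1.04 ± 0.85 in the epidermis. miR160 also went from 3.52 to 1.04 in the hilum and from 3.33 to 1.10 against the rest of the coat. With 4 and 0 reads in the 2 inner integument libraries, its standard errors were then 6.90 and 9.27, and 60.8 in the outer integument. For miR395 and miR399, with no read in the inner integument, the term could not be estimated (standard errors of 7277 to 13974). Their kept sign therefore carries no information. The embryo proper, outer integument and hilum share a layout, so differences among these 3, such as miR395 at 84.6 and 35.0 CPM in the outer integument and hilum with no read in the embryo proper, do not follow layout. Called sequences numbered 5168 in the embryo proper, 570 in the endosperm, 0 in the epidermis (6046 at an unadjusted p under 0.05), 3 in the outer integument, 3284 in the inner integument, 3 in the hilum, 12138 for the seed coat, 937 for embryo against endosperm, 4 for hilum against the coat and 23798 across subregions.

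Whether whole lists of families moved together was tested in 45 combinations of list and comparison. In the epidermis 5 lists were lower than other sequences (camera with a preset correlation of 0.01): the phasiRNA triggers (adjusted p = 0.000130; adjusted p = 0.515 with an estimated correlation), the other legume families (0.00206; 0.619), the developmental families (0.00696; 0.627), the small RNA machinery (0.00696; 0.515) and the nutrient and copper families (0.0130; 0.541). The nutrient and copper families were higher in the inner integument (adjusted p = 0.00558, and adjusted p = 0.515 with an estimated correlation), the subregion with the largest share of 5S rRNA ends (32.2%). The developmental families were higher in the hilum against all other subregions (adjusted p = 0.00696, and adjusted p = 0.621 with an estimated correlation) and against the rest of the coat (0.00558, and adjusted p = 0.621 with an estimated correlation). Without hilum 2, the library with embryo sequences at 12.8% of their embryo level, these were 0.0133 and 0.00400 with the preset correlation, and 0.0310 and 0.0903 with fry. With 1 library left out, the preset correlation kept all 8 calls in every set, except that of the nutrient and copper families in the epidermis (adjusted p = 0.127 without epidermis 1, kept in 10 of 12 sets). The preset correlation called 8 of 45, the estimated correlation 0 (4 at an unadjusted p under 0.05), and the rotation test fry 10, among them the developmental list in the hilum (adjusted p = 0.00853), the nutrient and copper list in the outer (0.00416) and inner integument (0.00301), and the phasiRNA triggers in the inner integument (0.0413). The direction of the test and the signs of the list's own changes differed in several lists that camera did not call. The phasiRNA triggers tested lower in the hilum with a positive mean and median, and lower against the rest of the coat with a positive mean and negative median. In the hilum the nutrient and copper list and the machinery list tested lower with positive means and negative medians. The developmental list tested higher in the endosperm with a positive mean and negative median, as did the machinery in the hilum against the rest of the coat, and the machinery tested lower in the inner integument with a positive mean and median. Against the filial parts, the coat's nutrient and copper list tested lower with positive mean and median, and its other legume list tested lower with a negative mean and positive median.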

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

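Layout of the files, reads per molecule, the near variant of miR156, lists with a library left out, leaving out the endosperm with epidermis 1, and leaving out rRNA ends were chosen after seeing the data. The other alternatives were fixed before. Of 1710 values for named families and sequences under alternatives other than a left-out library, 1437 kept direction and call, 258 lost the call and 15 reversed. With 1 library left out, 1799 of 2016 kept both, 215 lost the call and 2 reversed, both miR156/miR157 without hilum 2 (-2.84 in the hilum against the other subregions, with 4.68 without hilum 1, and -1.05 against the rest of the coat, with 6.46 without hilum 1). Unless stated, the cause was not tested.

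Family counts without 1 library ranged, against the main value, as follows: embryo proper 10 to 14 (11), endosperm 8 to 13 (12), epidermis 4 to 14 (13), outer integument 17 to 26 (13), inner integument 10 to 16 (15), hilum 10 to 15 (13), seed coat against filial parts 13 to 17 (17), embryo against endosperm 10 to 14 (14), hilum against the rest of the coat 7 to 11 (9), across subregions 29 to 32 (31). Sequence counts ranged from 11299 to 26953 (15498), 4507 to 11192 (7354), 133 to 3662 (2051), 4905 to 26636 (7502), 1176 to 4572 (4283), 1452 to 9398 (2325), 11618 to 22294 (15786), 4037 to 15592 (13971), 114 to 1197 (424) and 21154 to 48183 (25969) in the same order. Size classes ranged from 2 to 6 (4), first bases from 8 to 12 (12) and lists from 9 to 16 (8). A lone library was taken to vary like the other groups, and the filter's smallest group is then 1 library, so that 75311 to 83656 sequences were tested.

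Scaling moved log2 fold changes. Library size in place of TMM shifted them by -0.51 in the embryo proper, 0.26 in the epidermis, 0.44 in the outer integument, -0.25 in the inner integument, 0.34 for seed coat against filial parts and -0.39 for embryo against endosperm. Called sequences became 4924 in the epidermis, 12317 in the outer integument and 3628 in the hilum. RLE factors gave 12479 in the outer integument and 1355 in the hilum. Scaling to microRNA reads gave 8 families in the epidermis and 24 in the outer integument, reversed miR1507 (-0.11) and miR398 (-0.25) in the endosperm, and reversed miR167 (0.069) and miR1507 (0.26) between embryo and endosperm. Exact mature sequences reversed miR319 in the outer integument (-1.27). Counting TTGACAGAAGAGAGAGAGCAC in miR156/miR157 moved the family from -1.38 to 3.30 in the endosperm, where it then passed, and from 7.14 to 2.42 between embryo and endosperm, by construction, since that sequence is abundant in the endosperm. The family also went from -3.63 to -5.94 in the seed coat against filial parts, from 3.15 to 2.16 in the hilum and from -3.87 to -4.86 in the outer integument.

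DESeq2 called fewer sequences: endosperm 4898, epidermis 728, outer integument 4139, inner integument 1852, hilum 503, embryo against endosperm 7652, across subregions 16561. The weak filter, by construction with more sequences tested, gave 57768 in the embryo proper, 298 in the epidermis, 89394 in the outer integument, 1527 in the inner integument, 6275 in the hilum, 4731 (3792 higher) for embryo against endosperm and 51847 across subregions, with 8 families in the epidermis and 26 in the outer integument.

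The replicate number as a block gave 3 families and 682 sequences in the endosperm, 5 and 142 in the epidermis, 5 and 133 in the hilum, 5 and 901 for seed coat against filial parts, and 9 and 4355 for embryo against endosperm. No endosperm family was then higher, against 9 of 12, and 2 of the 3 were called in the main fit. Number 3 occurs in the endosperm alone, so by construction the block leaves its level to endosperm 4. The block gave 1214 sequences in the outer and 1116 in the inner integument, 688 for hilum against the rest of the coat and 15368 across subregions. The majority of called sequences turned to lower in the outer integument (466 higher and 748 lower) and the seed coat (191 and 710), and the epidermis had 75 and 67. miR2119 in the endosperm went from 4.02 to -0.70 (adjusted p = 1.00), fitted with 2 reads in the embryo proper, and miR1508 in the seed coat went from -1.55 to 0.54. In the 4 coat subregions, numbered 1 and 2, deviations of libraries with the same number correlated between -0.008 and 0.098. Embryo proper and endosperm, which share number 4, correlated at 0.082, and the embryo proper and coat, which share number 1, between -0.009 and 0.071. These correlations are low, but no reference for libraries without a shared number was computed, so pairing cannot be excluded.

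A term for file layout left 5168 sequences in the embryo proper (1402 higher), 4 families and 570 sequences in the endosperm, 0 and 0 in the epidermis, 0 and 3 in the outer integument, 1 and 3 in the hilum, 5 and 937 (187 higher) for embryo against endosperm, and 0 and 4 for hilum against the rest of the coat (edgeR, where the unadjusted p was under 0.05 for 9 families and 6046 sequences in the epidermis, 10 families in the outer integument and 10 for hilum against the rest of the coat). By construction the term is estimated from the 2 inner integument libraries alone, since every other subregion came in 1 layout. Those 2 libraries also differed in sequences read once (57.3% and 29.7%). All named families kept their sign, though for miR395 and miR399 the term could not be estimated. Median standard errors grew from 0.49 to 0.85 in the outer integument and from 0.54 to 0.98 in the hilum, but some changes also shrank, as for miR160 in the seed coat (1.32 ± 0.54 to 0.13 ± 0.44). Dividing by reads per molecule gave 4306 sequences in the endosperm, 2657 in the inner integument, 8796 for embryo against endosperm and 21 families in the outer integument. Without the endosperm and epidermis 1, the embryo proper had 18 families and 38420 sequences, the epidermis 6 and 118, the outer integument 25 and 23913, seed coat against the embryo proper alone 38420 sequences with miR165/miR166 at 0.30, and hilum against the rest of the coat 654 sequences.

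Within the libraries whose labels describe the dissection, coat against filial parts gave 11 families, with miR390 at -1.68, miR160 at -1.07 and miR165/miR166 at 1.28. Within the others miR396 was at -3.70, miR2119 at -2.27, miR156/miR157 at 0.91 and miR319 at 0.84. By construction each uses fewer subregions. Size classes past the threshold were 9 for distinct sequences, 9 without the 10 most abundant sequences and 7 without rRNA ends, against 4. First bases were 6 of 12 without the 10 most abundant. Lists called were 0 of 45 with an estimated correlation (4 at an unadjusted p under 0.05), 8 with the preset one and 10 with fry.

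Analyses of chalcone synthase siRNAs, tRNA and rRNA fragments and genomic windows were not run. With only the groups compared, seed coat against filial parts uses all 12 libraries and gives no other value. Depth limits the families with few reads: miR172, miR393, miR395, miR397, miR399 and miR2111 had no read in at least 1 subregion.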

Other observations

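The forms within families differed between parts of the seed. These tests were chosen after seeing the data. In the outer and inner integument TCTCGGACCAGGCTTCATTCC made up 27.3 ± 5.12% and 28.2 ± 2.79% of miR165/miR166 reads, against 0.512% to 7.05% in libraries of the other subregions (adjusted exact p = 0.0192, 2 libraries per subregion, 8 tests), and the main form TCGGACCAGGCTTCATTCCCC made up 55.2 ± 4.05% and 56.4 ± 4.2%, against 81.1% to 97.3% (adjusted exact p = 0.010). miR165/miR166 limits class III HD-ZIP factors, and forms that start at another base pair with targets at a shifted seed.

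The share of GGAATGGGCTGATTGGGAAGC, from the arm opposite to the listed miR482, was 1.70 ± 0.612% in the embryo proper and 1.2 ± 0.888% in the inner integument, against 40.7% to 90.3% in the other subregions (adjusted exact p = 0.0192). AGGGATAGGTAAAACAATGAC, from the arm opposite to miR1510, made up 94.0% to 99.4% everywhere (adjusted exact p = 0.557). In the endosperm TTGACAGAAGAGAGAGAGCAC, with T14A relative to the listed miR156 (positions from 1 at its 5′ end), reached 715 ± 235 CPM, and CATGTGCCCCCCTTCCCCATC, 4 differences from the opposite strand of miR164, reached 5026 ± 3048 CPM. Neither was counted in a listed family.

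The patterns weighed next were noticed in the data, and each prediction was written down before its test was run. The high miR156/miR157 in hilum 2 may come from embryo tissue in that library. If so, other embryo sequences should be raised with it: over 170 sequences with at least 10 CPM in both embryo libraries and levels more than 20-fold lower in the 8 libraries outside embryo and hilum, the median log2 ratio of hilum 2 to hilum 1 was 2.72 (quartiles 1.80 and 3.40), and 93.5% were at least 2-fold higher in hilum 2, which excludes a rise of miR156/miR157 alone. Their median level in hilum 2 was 12.8% of that in the embryo, near the 19.3% of miR156/miR157, against 0.230% in hilum 1. The 292 sequences specific to the endosperm, chosen in the same way, had a median of 0% in both hilum libraries. Embryo material in hilum 2, from tissue or from RNA, is consistent with these values, and its route was not tested.

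Few sequences read once in the endosperm and epidermis 1 might come from PCR copies of few molecules or from a small set of abundant siRNAs. The recurrence of 24-nt sequences read 3 times in 1 library of a subregion was compared with the Poisson rate in the other, and reached 9.24% and 16.7% of that rate in the endosperm. It was also low in every other subregion, up to 65.3% in the outer integument. Separate libraries differ by more than counting error for any reason, so this comparison decides for neither explanation. The most frequent count of a 24-nt sequence was 2 in endosperm 3, 3 in endosperm 4 and epidermis 1, and 1 in every other library. Sequences read once were 14.1% in epidermis 1 but 58.7% in epidermis 2, so in the epidermis the pattern did not follow the subregion. In the endosperm, where both libraries share it, both explanations stay open.

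Distinct 22-nt sequences were a larger share in the embryo proper (11.2 ± 0.647%), endosperm (10.0 ± 0.356%) and inner integument (9.65 ± 0.346%) than in the hilum (7.79 ± 1.27%), epidermis (6.14 ± 0.825%) and outer integument (6.13 ± 0.142%; adjusted exact p = 0.00481). Shortened 24-nt siRNAs could account for the embryo's share. Of its 22-nt sequences 33.1% and 33.8% lay inside a 24-nt sequence of the same library, against 46.6% and 41.6% in the outer integument. The embryo's values fell between the limits set beforehand for and against shortening, so the test does not decide. Without the 22-nt sequences inside a 24-nt one, a share that was not part of the prediction, the embryo had 7.18% and 7.71%. The endosperm had 7.35% and 7.15%, the inner integument 6.27% and 7.58%, and the hilum, epidermis and outer integument libraries 3.22% to 6.19%. This share depends on how many 24-nt sequences were read, and copies of 24-nt sequences that were not read remain in it, so shortening stays open. Opposite-strand partners with a 2-nt overhang, as Dicer leaves, were found 0.904 times as often as those at the most frequent other overhang, so the predicted excess from 22-nt duplexes was not found. Every library was then thinned to 1072232 reads outside listed families and rRNA ends. The lower embryo share still exceeded the highest of the hilum, epidermis and outer integument libraries by 1.68 percentage points (10.3% and 11.2% in the embryo libraries). Read depth alone therefore does not account for the difference. Thinning evens out reads and not molecules, and left 178900 to 639732 distinct sequences per library, so PCR copies, also named in the prediction, stay open.

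The split into seed coat and filial parts was set against other splits of the 12 libraries into 8 and 4, 100 in all with the real one. The real split called 17 families and 15786 sequences, and the highest other split 9 families and 5256 sequences, so that 1 of 100 splits did as well for either count. Such splits part the replicates of a subregion, which by itself lowers their counts, so the comparison does not decide whether chance can be excluded. Keeping subregions whole gives 15 groupings, too few for a share under 0.05: the embryo proper with the epidermis, the libraries whose labels describe the dissection, or the outer with the inner integument, against the rest, also called 17 families, and the highest other count of sequences was 9925.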
